A study of Rattus norvegicus with 24 samples.

How the data were processed

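Sperm from the cauda epididymis of 24 male Wistar rats was assayed by reduced representation bisulfite sequencing, which reads cytosine methylation at CpG-rich restriction fragments. The animals formed 4 groups of 6: offspring of vehicle-fed dams at postnatal day (PND) 65 and PND120, and offspring of BDE-47-fed dams at the same ages. BDE-47 is a brominated flame retardant, and the dams received 0.2 mg/kg body weight per day from pregnancy day 8 until PND21, per the labels. One pup per litter was taken at each age, so animals of different ages in an exposure arm can be littermates, and the columns used here do not say which. The sperm had been passed through a density gradient to remove somatic cells, per the labels.

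Per the series' design text, reads were mapped to the rat assembly rn6 with Bismark 0.16.1 and Bowtie2 2.2.9, PCR duplicates were removed with nudup 2.2, and only CpGs with at least 10 reads were kept. Differentially methylated regions (DMRs) were called with MethPipe, and the nearest gene was added with closest-features 2.4.25, per the same text. Both tables analysed here are the authors' own DMR lists. Per the file headers, listed regions had q under 0.05 and at least 3 CpGs, and the exposure table also required a change of 5 percentage points. Every region of the age table differed with age by at least 5 points in controls or in BDE-47 animals. The age table holds each group's methylation level as a fraction from 0 to 1, deposited by the authors as 1 value per group and region, and 2 columns of differences in percentage points. These differences equalled 100 times the difference of the fractions, with a largest gap of 1.07e-14 points. The exposure table holds a signed change in percentage points, whose direction its header does not state. Its header calls the samples mouse, while the labels give rat.

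Of the 11 columns used, 0 hold values of single animals. No replicate spread, region depth or p-value of a region could therefore be computed, group levels are printed as the authors' value without SD, and the depth of each library is unknown. The p-values below compare regions within a list, list genes with all annotated genes, or overlaps with random placements, and none compares animals. Regions are not replicates, neighbouring regions share reads and animals, and such p-values say nothing of the spread between animals. Intervals of shares are exact Clopper-Pearson 95% intervals over regions.

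Fractions were multiplied by 100 to give percent. Gains and losses were counted from the sign of the control difference. The size of gains and losses was compared with a two-sided permutation test of medians with 100000 resamples. A region was placed in a gene body where the authors' distance was 0, upstream where it lay within 1 kb before the gene by strand, and otherwise in the remaining intergenic class. A positive distance was read as a gene at higher coordinates, a reading with 0 mismatches among the 30 exposure rows, which give gene coordinates. Gains and losses were compared in their share of each class with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Exposure DMRs were placed at random on their chromosome 10000 times, within the span of listed regions, to give a one-sided p for overlap with age DMRs. Coordinates are printed as the tables give them, on rn6, and the tables do not say whether starts count from 0 or 1.

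Before the data were examined, 12 gene lists were fixed. They cover homeobox and patterning transcription factors, developmental signalling (Wnt, Hedgehog, BMP, FGF and Notch), DNA methylation and chromatin modifiers, cell adhesion and protocadherins, synaptic and neuronal excitability, and insulin, mTOR and nutrient signalling. The others cover spermatogenesis and sperm function, the thyroid hormone and steroid axis, xenobiotic sensing and metabolism, germline genes methylated in somatic cells, and imprinted genes with maternal or with paternal germline methylation. Gene symbols were matched to RefSeq names of assembly GRCr8, used for names only. Of 4131 genes in the age table, 3617 matched a current symbol and a further 158 an older one. Each list was tested for its share of gains against all other regions. A second test, one-sided, compared the share of list genes with an age DMR with that of all 23154 annotated protein-coding genes. The assay covers CpG-rich sequence, and a background of covered genes was not used here, so this second test also measures how CpG-rich a list is.

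Named regions followed a rule fixed before the data were examined: the 10 largest gains and 10 largest losses in controls, the 5 genes with the most age DMRs, up to 4 genes per list by size of change, and every exposure DMR. A gene tied at the limit was not separated from its ties, and some genes that the rule names are not reported here. Classes of PND65 control level (under 10%, 10 to 30%, at least 30%), the comparison of both exposure arms at the age regions and the regions changed in both arms were chosen after the data were seen; there an exact sign test across regions gave the side of the threshold for each alternative. The alternatives tried were a change of at least 20 points, at least 10 CpGs, at least 100 bp, autosomes alone, regions within 1 kb merged, a 5 kb upstream window, and other overlap and gene distances. Added after the data were seen were regions of at most 1 kb, the level classes, a 10 kb limit on gene distance, and the exposure column with its sign turned. The overlap step was tested with planted intervals and the age table's 5327 regions, and 12 of 12 planted overlaps were recovered. The permutation test was tried on sets drawn from the gains, with fewer gains and fewer resamples than in the main test. There a shift of 3 points was called in 100% of 100 repeats, against 3% without a shift. A shift as small as the observed 1.21 points was not simulated. The rn6 genome was not used here, so an expectation per chromosome and a background of coverable fragments were not computed. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.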

Results

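Sperm DNA methylation was compared in 24 rats, 6 in each of 4 groups defined by age (PND65 or PND120) and by maternal feeding with vehicle or BDE-47. The authors' deposited tables list 5327 age DMRs with the methylation level of every group and 30 exposure DMRs. CpGs had at least 10 reads, and the depth of single regions and the spread between animals are unknown. The age DMRs held a median of 4 CpGs and were a median of 155 bp long. Of these regions, 1461 were longer than 1 kb and 157 longer than 100 kb, so the gene given for a long region is only one of those it may span.

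The first comparison asked how sperm methylation differed between PND65 and PND120 in control animals. Nearly every listed region gained methylation with age: 5287 regions gained and 40 lost, a share of gains of 99.2% (95% interval 99.0 to 99.5). Most gains lay in sequence that was almost unmethylated in PND65 controls. At 4166 of the gained regions the PND65 control level was under 10%, and there the median over regions was 0.624% at PND65 and 11.3% at PND120. The median gain over all gained regions was 9.33 points, with quartiles of 7.63 and 11.6.

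The largest gains in the authors' deposited table lay in regions of intermediate methylation. At Lrrc8e, a subunit of volume-regulated anion channels, a gene-body region on chromosome 12 from 2558530 to 2563993 with 14 CpGs went from 36.6% to 84.1%. Beside Mapk13, which encodes the p38 delta MAP kinase, a region of 3 CpGs on chromosome 20 from 6027644 to 6027776, 178 bp from the gene, went from 40.7% to 87.6%. The authors' deposited table gives gains of 28.6 points at Adat3, a subunit of a tRNA adenosine deaminase, 25.6 points at the RNA-binding protein gene Mex3a and 25.6 points at LOC500956. Gains of 23.0 to 25.0 points were listed in that deposited table at Setd1b, a histone H3 lysine 4 methyltransferase, at Tmem231 of the ciliary transition zone, at the acid phosphatase Acp5 and at Zc3h4. The Tmem231 region differed from the others in this set, with a PND65 control level of 1.03% and a PND120 level of 26.1%.

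Losses with age were few and began from higher levels, with a median PND65 control level of 57.9% over the 40 regions. In the authors' deposited table, methylation fell by 31.7 points in a region on chromosome 16 from 83685479 to 83685614, 53327 bp from the type IV collagen gene Col4a1. In the authors' deposited table it fell by 20.7 points in the gene body of the small GTPase Rab20 on the same chromosome, by 20.4 points at LOC103693172 and by 17.9 points at Pls1, which encodes the actin-bundling protein plastin 1. The other losses in this set of the authors' deposited table, from Ccni, which fell by 16.5 points, to LOC102546845, which fell by 13.4 points, included Hipk3, RGD1561808, Baalc and the endocytic adaptor gene Ston2. Losses were larger than gains by 1.21 points in the median (permutation p = 0.0380, two-sided, across regions), a call that was lost in regions of at least 100 bp (p = 0.198) or with at least 10 CpGs (p = 0.174). The difference turned to -0.601 points with changes of at least 20 points, where 3 losses were left (permutation p = 0.544).

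Gains lay in gene bodies more often than losses, 79.9% against 60% (Fisher's exact test, adjusted p = 0.00683), and 8.89% of gains against 35.0% of losses were in the remaining intergenic class (adjusted p = 1.64e-05). The upstream class held 11.3% of gains and 5.00% of losses (Fisher's exact test, adjusted p = 0.312). Among regions with at least 10 CpGs, which hold 7 losses, neither difference passed the threshold and the intergenic one turned, and neither passed with changes of at least 20 points. By chromosome, the count of age DMRs ran from 616 on chromosome 1 to 42 on chromosome X, of which 41 gained.

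Some genes carried several age DMRs. Nr2e1, an orphan nuclear receptor of neural stem cells, Ptch1, the Hedgehog receptor, and the zinc-finger repressor gene Zbtb7a had 7 each, all gains, and Skor1 had 6, all gains. A further 9 genes had 5 each, among them Bahd1, Barhl2, Ece2, Egr4, Foxb1, Tnrc18, Trim36 and Zswim6. In the authors' deposited table the gains at and near Ptch1 ran from 7.67 to 14.2 points.

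Developmental regulators had an age DMR more often than annotated genes in general. Of 147 annotated homeobox and patterning transcription factors, 86 had an age DMR (58.5%), against 15.7% of all annotated protein-coding genes (one-sided Fisher's exact test, adjusted p = 2.62e-31), and 153 of the 155 regions gained. The authors' deposited table gives gains of 20.5 points at Tbx3, 18.8 points at Hoxb9 and 16.6 points at Six6. In the developmental signalling list 67 of 122 genes had an age DMR (54.9%, adjusted p = 1.35e-22) and 101 of 102 regions gained, with 21.1 points at Wnt10b, 16.2 points at Bmp1 and 14.8 points at Lef1 in the authors' deposited table. Because the assay favours CpG-rich sequence, and these genes are CpG-rich, these shares do not separate age from coverage.

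Chromatin and DNA methylation modifiers had an age DMR at 35 of 112 annotated genes (31.2%, Fisher's exact test, adjusted p = 6.07e-05), and all 53 regions gained. Besides Setd1b, the authors' deposited table gives 18.5 points at Uhrf1, which guides maintenance methylation to replicated DNA, 17.7 points upstream of the methyltransferase gene Kmt2a and 17.0 points at the demethylase gene Kdm2a. Insulin, mTOR and nutrient signalling genes had an age DMR at 26 of 63 members (41.3%, adjusted p = 3.23e-06), with all 41 regions gaining and, in the authors' deposited table, 17.5 points at Foxo6, 14.3 points at Pik3r1, 14.0 points at Sesn2 and 13.5 points at Gsk3b. Synaptic genes had an age DMR at 41 of 122 (33.6%, adjusted p = 3.23e-06), all 61 regions gaining, with 19.5 points at the adhesion protein gene Nlgn3, 18.0 points at Shank1, 16.0 points at the GABA receptor gene Gabbr2 and 14.3 points at the calcium channel gene Cacna1h in the authors' deposited table. Adhesion genes had an age DMR at 27 of 75 (36.0%, Fisher's exact test, adjusted p = 3.48e-05), with 38 gains and the Col4a1 loss. Their gains in the authors' deposited table included 20.6 points at Pcdh17, 17.8 points at Pcdh9 and 15.8 points at the laminin gene Lama5.

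The remaining lists held few age DMRs, and none passed the enrichment test. Spermatogenesis and sperm function genes had one at 10 of 80 members, with 11 gains, among them 12.7 points at Zpbp2, 11.9 points at the testis kinase gene Tssk6, 10.8 points in a region 64117 bp from Pmfbp1 and 10.4 points at the sperm calcium channel gene Catsper2 in the authors' deposited table. The thyroid and steroid list had 9 gains at 5 of 48 genes, with 12.4 points at Inhbb, 11.9 points at the thyroid hormone receptor gene Thrb, 9.46 points at the mineralocorticoid receptor gene Nr3c2 and 7.13 points at Nr5a1 in the authors' deposited table. The xenobiotic list had 7 gains at 7 of 47 genes, with 14.9 points at Ppara, 10.8 points at Nfe2l2, 10.6 points at Pparg and 10.5 points at the monooxygenase gene Cyp1a1 in the authors' deposited table. Germline genes methylated in somatic cells had an age DMR at 2 of 52 members, Tdrd6 (7.17 points) and Zfp42 (6.08 points, 1191 bp from the gene, in the authors' deposited table), maternally imprinted genes at 2 of 29, Nnat (13.2 points, 8121 bp from the gene) and Trappc9 (12.5 points), and paternally imprinted genes at 0 of 7. The share of gains differed from other regions in 0 of the 11 lists with an age DMR by Fisher's exact test, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 1. With only 40 losses among 5327 regions, a higher share of gains could not have passed in lists of this size. The test could only have found an excess of losses.

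**Figure D1:**
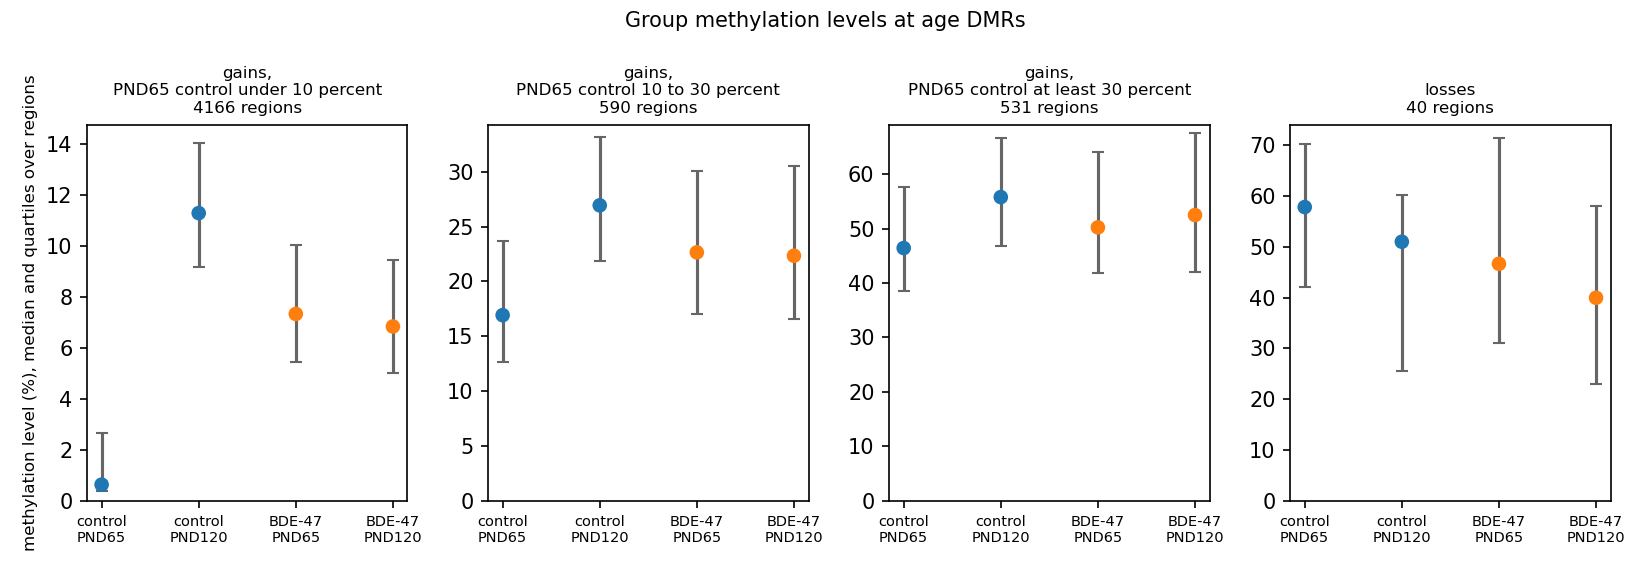
Median methylation level in percent (points) with lower and upper quartiles over regions (bars) for the 4 groups, at gained regions in 3 classes of PND65 control level and at the 40 lost regions; each panel has its own vertical scale. In the lowest class the control medians are 0.624% and 11.3%, and the BDE-47 medians are 7.33% and 6.83%.

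The second comparison set the BDE-47 animals beside the controls at the same regions. At regions gained from low levels, BDE-47 animals had intermediate methylation at both ages and little difference between ages. At the 4166 gained regions with a PND65 control level under 10%, the authors' values had medians of 7.33% at PND65 and 6.83% at PND120 in BDE-47 animals, against 0.624% and 11.3% in controls. Over all gained regions the median age difference was 9.33 points in controls and -0.379 points in BDE-47 animals. At Uhrf1, the levels were 0.603% and 19.1% in controls at PND65 and PND120 and 12.7% and 12.0% in BDE-47 animals, and at Hoxb9 they were 0.357%, 19.1%, 12.5% and 14.0% in the same order.

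At PND65 the BDE-47 level was above the control level in 4990 of the 5327 regions (93.7%), with a median difference of 5.65 points, and at PND120 it was below the control level in 4805 regions (90.2%), with a median difference of -4.11 points. The BDE-47 level lay between the control levels of both ages in 4494 regions at PND65 and 4519 at PND120. In 5316 of the regions the controls differed with age by at least 5 points, and in the other 11 only the BDE-47 animals did. Where a region is listed for its control difference, chance error in either control group pulls an unrelated group between them, and the spread between animals that would measure this is unknown. In regions with a PND65 control level of at least 30%, the median age difference in BDE-47 animals among gained regions was 0.650 points, of the opposite sign, and 48.4% and 47.5% of these lay between the control levels at PND65 and PND120. At the 40 lost regions the median BDE-47 age difference was -8.12 points, and 52.5% and 40% lay between.

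Another set of regions moved alike in both arms. In 154 regions the age difference was at least 5 points with the same sign in controls and BDE-47 animals, 133 of them gains and 21 losses. Shuffling the BDE-47 differences among regions of like PND65 control level gave a mean of 129.7 such regions, 127.9 gains (118 to 136) and 1.81 losses (0 to 8). Since only 137 regions gained at least 5 points in BDE-47 animals and nearly all regions gained in controls, the count of gains says little on agreement. At the 528 regions that gained at least 5 points in controls from a PND65 level of at least 30%, the age differences of both arms correlated with a Spearman rho of 0.392 (Pearson r 0.705, across regions). In the authors' deposited table, the BDE-47 difference was 42.2 points at Lrrc8e, 31.98 points at Mapk13, 22.7 points at Adat3, 24.1 points at LOC500956, 20.0 points at Mex3a and 27.6 points at Setd1b. Other large control gains had a small BDE-47 difference in that deposited table, 5.39 points at Acp5, 6.18 points at Zc3h4 and -1.13 points at Tmem231. At the losses the difference in BDE-47 animals was -35.3 points near Col4a1, -17.9 points at Rab20, -24.2 points at LOC103693172, -13.8 points at Pls1, -18.3 points near Hipk3 and -22.7 points at Ston2 in the authors' deposited table. At the other losses named above, that deposited table gives 0.160 points near Ccni, -4.24 points at Baalc, -9.41 points near RGD1561808 and -8.61 points near LOC102546845 in BDE-47 animals. Of 178 regions that moved by at least 5 points in both arms, 133 gained in both, 21 lost in both, 24 gained in controls and lost in BDE-47 animals, and 0 did the reverse (Fisher's exact test, two-sided, p = 3.63e-15, across regions). A gain of at least 5 points in both arms was found in 106 of 531 gained regions with a PND65 control level of at least 30% (20.0%) and in 7 of 4166 with a level under 10% (0.168%; Fisher's exact test, two-sided, p = 3.74e-95, across regions). Because all these regions gained in controls, that test compares where BDE-47 levels rose and does not measure agreement between arms.

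**Figure D2:**
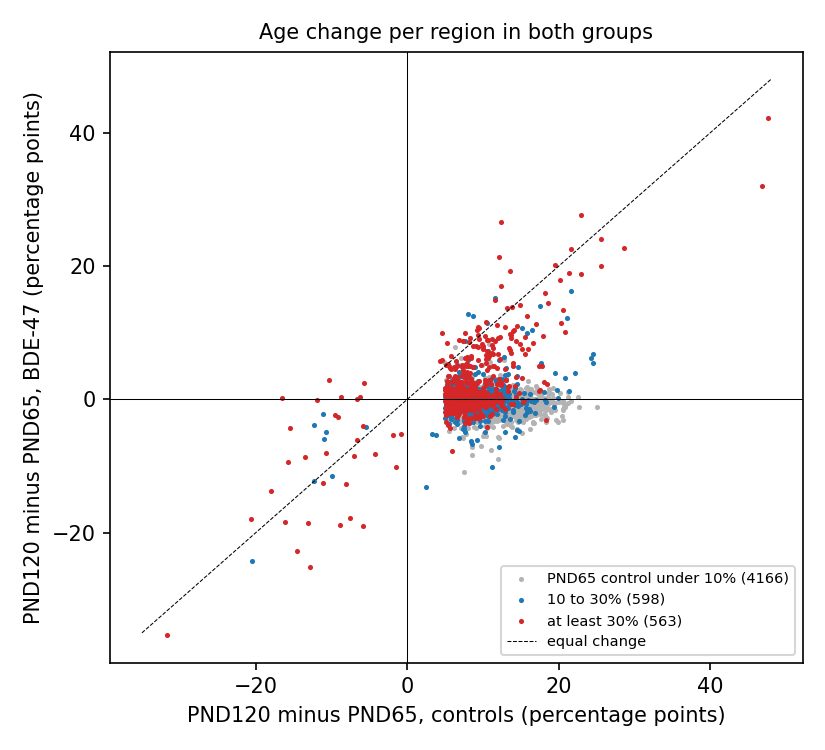
Difference in methylation between PND120 and PND65 in percentage points, in controls (horizontal) and BDE-47 animals (vertical), 1 point per age DMR, coloured by PND65 control level; the dashed line marks equal change. Regions of low PND65 level lie along a BDE-47 difference near 0, and 123 of the 154 regions that moved alike in both arms started from at least 30%.

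The third comparison asked which regions differed between BDE-47 and control sperm of the same age. The authors' deposited exposure table lists 21 regions at PND65, of which 16 have a negative and 5 a positive change, and 9 at PND120, of which 2 are negative and 7 positive. The direction of the change column is not stated. It was read as BDE-47 minus control from the only region that both tables share. There an exposure region of 3 CpGs, ending at 50616694, partly overlaps a longer age DMR of 11 CpGs that ends at 50616657. How many CpGs the 2 have in common is unknown, and every direction given for this table depends on that reading of the sign. With the sign turned, 16 of 21 regions would be higher in BDE-47 animals at PND65 (76.2%) and 2 of 9 at PND120 (22.2%). The turned shares go the way of the age DMRs, where BDE-47 levels were higher in 93.7% of regions at PND65 and lower in 90.2% at PND120. Apart from the shared region those are other regions, so the sign stays open. As read, the share of higher regions was 23.8% (95% interval 8.22 to 47.2) at PND65 (exact binomial test, two-sided, p = 0.0266) and 77.8% (40.0 to 97.2) at PND120 (p = 0.180). It differed between the days (Fisher's exact test, two-sided, p = 0.0125, across regions), whichever way the sign is read. With a change of at least 20 points the shares were 42.9% and 50% (Fisher's exact test, p = 1), and with at least 10 CpGs, which leaves 3 regions, the difference turned.

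At PND65 the authors' deposited table gives the largest differences as 40.0 points near the zinc-finger gene Zfp407, on chromosome 18 from 81018205 to 81018654 and 38.9 kb from the gene, and -36.9 points near LOC102550426. The others with a positive change in that deposited table lay near LOC365605 (30.98 points) and RGD1565735 (24.5 points) and in Gbas (18.8 points) and the lens crystallin gene Cryga (5.00 points). Negative changes were listed in the authors' deposited table at LOC100909844 (-35.4 points), 20.8 kb from the endothelial sialomucin gene Emcn (-34.0 points), near LOC102552357 (-21.3 points) and LOC502984 (-18.0 points), and in the gene bodies of LOC103692942 (-16.7 points) and the teneurin gene Tenm2 (-15.1 points). They were also listed there near LOC103693375 (-14.0 points), in Tnfaip3, which encodes the NF-kB inhibitor A20 (-13.4 points), near LOC102547965 (-12.8 points), in the protocadherin gene Pcdh15 (-11.4 points), and near LOC103691984 (-8.43 points). The smallest negative changes in the authors' deposited table were -8.38 points 34.5 kb from the kinase gene Nuak1, -7.46 points 51.2 kb from the heart and limb transcription factor gene Tbx5, -7.22 points in Acads, which encodes an acyl-CoA dehydrogenase of fatty acid oxidation, and -7.10 points in LOC690289.

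At PND120 the authors' deposited table gives 40.9 points near Zfp407, 24.1 points near LOC100362780, 18.4 points in the non-muscle myosin gene Myh14, 17.0 points near LOC102550954, 11.9 points near Tp53rk, 10.5 points in the immunity-related GTPase gene Irgm and 10.0 points near the iron transporter gene Slc11a2. The 2 negative changes in that deposited table were in Slc46a3 (-27.3 points, 14 CpGs) and LOC100909844 (-25.4 points). The regions near Zfp407 and at LOC100909844 were listed at both days, with the same sign each time, and these were the only 2 of the 21 PND65 regions that overlapped a PND120 region.

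**Figure D3:**
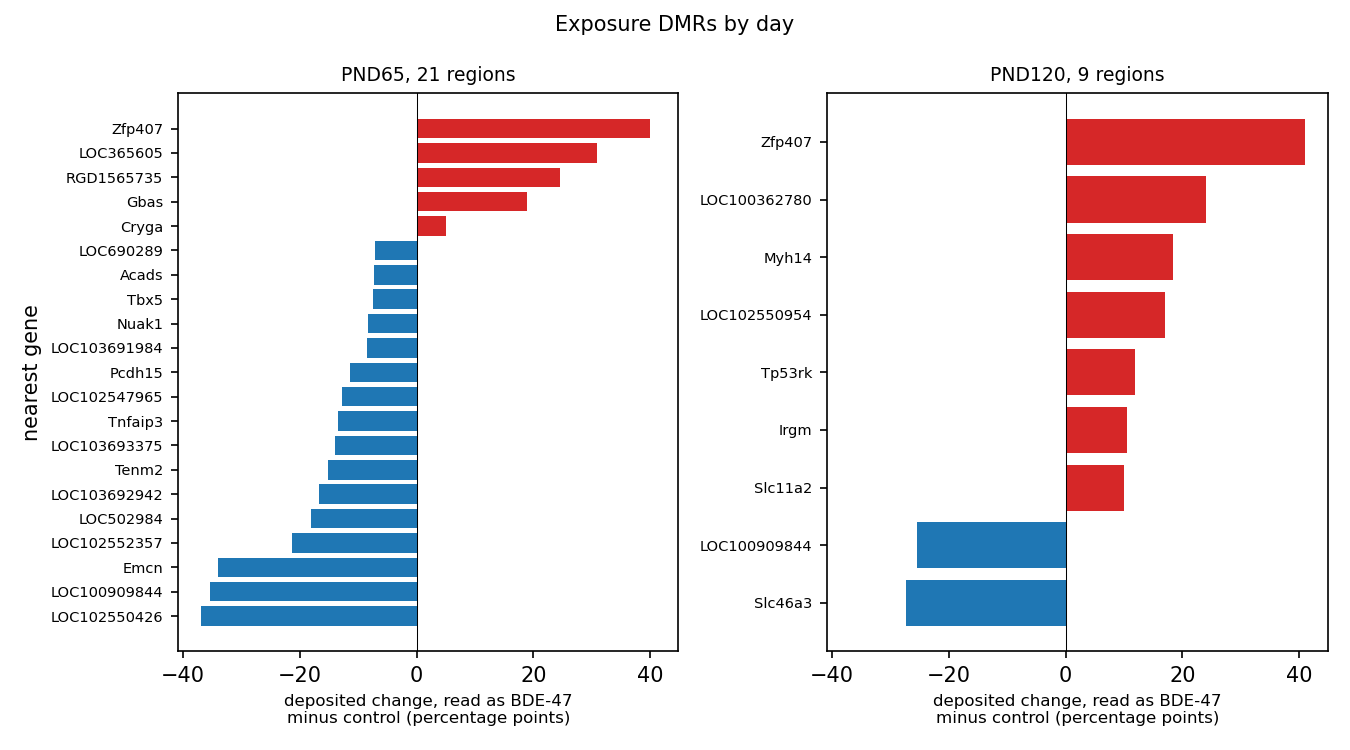
Deposited change in methylation in percentage points, read as BDE-47 minus control (bars, from 0), for each exposure DMR at PND65 and PND120, named by the nearest gene. Of the PND65 regions 16 lie below 0, and of the PND120 regions 7 lie above it.

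The last comparison asked whether exposure and age touched the same regions. Of the 30 exposure DMRs, 1 overlapped an age DMR, the PND65 region near LOC365605, against a mean of 0.928 in random placements (permutation p = 0.614, one-sided). The placements fell anywhere in the span of listed regions, not only in sequence that the assay covers. The mean and the p therefore do not measure chance overlap among covered regions. By day, 1 of 21 overlapped at PND65 (permutation p = 0.485) and 0 of 9 at PND120 (p = 1). That region gained with age in controls, by 5.49 points in the authors' deposited table. It also set the sign of the exposure column, so its direction there is no evidence, and with a single overlap the directions could not be tested. Both contrasts use the same control animals, and the effect of sharing them could not be simulated without values per animal. Of 5 genes named in both tables, LOC365605 and Slc11a2 had a positive change in both, and Tbx5, Nuak1 and Slc46a3 a negative exposure change and a gain with age in controls, and all of these exposure directions turn with the sign of the column.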

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

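The share of exposure DMRs with a positive change stood out because it differed between the days, 5 of 21 at PND65 against 7 of 9 at PND120 (Fisher's exact test, two-sided, p = 0.0125, across regions). Leaving out the 2 regions listed at both days gave 4 of 19 against 6 of 7 (Fisher's exact test, two-sided, p = 0.00529). Which group is higher is not stated for this column: read as BDE-47 minus control, these regions are higher in BDE-47 animals, and with the sign turned 16 of 21 would be higher at PND65 and 2 of 9 at PND120. Regions are not replicates, and no test over animals was made.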

How the results depend on the processing

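Of 58 recomputed values, 36 kept their direction and their side of the threshold or their range, 7 lost the call, 10 moved and 5 turned. The share of gains among age DMRs was 92.9% with changes of at least 20 points, 98.8% with at least 10 CpGs and again 98.8% with at least 100 bp. Added after the data were seen, it was 99.8% in regions of at most 1 kb and 72.5% among regions with a BDE-47 age difference of at least 5 points, taken by that difference. Losses minus gains in size came to -0.601 points with changes of at least 20 points, where 3 losses were left, 1.38 points with at least 10 CpGs and 0.801 points with at least 100 bp, none past the threshold. Losses minus gains in the gene-body share was -20.5 percentage points and in the intergenic share 25.6 with changes of at least 20 points, and -2.44 and -7.90 with at least 10 CpGs, none past the threshold, with 3 and 7 losses tested. The share of higher exposure DMRs at PND120 minus PND65 was 7.14 percentage points with changes of at least 20 points (11 regions) and -50 with at least 10 CpGs (3 regions), and -54.0 with the unstated sign of the column turned, an alternative added after the data were seen. Genes whose exposure and age regions had the same sign numbered 2 by assigned gene and 3 with that sign turned, against 1 overlapping region, which had set the sign. The alternatives for the next values were added after the data were seen. The median BDE-47 age difference at gained regions was -0.115 points with at least 10 CpGs, no longer past the threshold, and 0.650 points at a PND65 control level of at least 30%. Regions that moved alike in both arms numbered 23 at lengths of at most 1 kb, 66 with at least 10 CpGs and 7 at a PND65 control level under 10%. Apart from the smaller numbers of regions, the cause was not tested. The count of lists whose share of gains differed stayed at 0 under the 3 alternatives run, where the few losses left a higher share of gains no room to pass. In the comparison with annotated genes 6 lists passed with all regions and with regions in or upstream of a gene. Expectations per chromosome, random places among coverable fragments and the coverable-gene background were not run, since they need the rn6 sequence, and leaving out single animals was not run because the columns used hold groups. No paired analysis was possible because the columns carry no animals. The depth of each region is unknown, and regions of 3 or 4 CpGs limit the precision of single values.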

Other observations

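All tests in this part were chosen after the data were seen.

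Besides the short exposure list, 50 age DMRs showed a difference of at least 20 points between BDE-47 and control animals with the same sign at both ages, 20 lower and 30 higher with BDE-47. None of these regions overlapped a region of the exposure table. At Cdh7, a cadherin gene, the authors' values were 72.7% and 60.8% in controls at PND65 and PND120 and 20.7% and 20.6% in BDE-47 animals. That region holds 4 CpGs over 331204 bp. At Fem1a they were 48.1% and 59.3% in controls and 97.1% and 97.0% in BDE-47 animals, and at the synaptotagmin gene Syt7 45.8%, 50.4%, 83.9% and 93.8%. Of these regions 34 are over 10 kb and 9 at most 1 kb long, and they rest on a median of 4 CpGs. They were chosen for this difference, which was not tested between animals.

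At 3190 age DMRs the BDE-47 level was at least 5 points above the control level at PND65, and at 124 it was at least 5 points below, while the authors' exposure table lists 21 regions at that age. The counts 3190 and 124 are differences of group levels without a test, in regions listed for age and mostly low in PND65 controls. The 21 regions passed q under 0.05 for exposure, so the numbers are not alike in kind. Of the 21 regions, 16 have a negative change, which is lower with BDE-47 as the column was read and higher if its unstated sign is turned.

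The first pattern weighed is the gain in nearly unmethylated regions of controls, with BDE-47 animals between the control ages. Independent error at single regions, of equal size in both control groups, would list as many losses as gains. Of the regions with a control change of at least 5 points, 99.3% gained. Spread and depth of the groups are unknown, so this share does not exclude larger error in PND120 controls alone, where levels near the floor can only be raised. A single rate of incomplete bisulfite conversion per library would leave no reproducible differences between regions, yet over 3001 regions under 2% in PND65 controls the BDE-47 levels of the 2 ages, from different animals, correlated with a Spearman rho of 0.919 (bootstrap interval 0.911 to 0.926, Pearson r 0.9497, across regions), and PND120 control levels correlated with those of PND65 BDE-47 animals with a rho of 0.637 (0.609 to 0.663). PND65 and PND120 control levels had a rho of 0.105 (0.0713 to 0.140) over this narrow PND65 range. If the libraries of a group count alike at every region, these correlations argue against a uniform rate as the whole control gain, and not as part of it. How much each library counts at a region is unknown, so libraries of unlike rate and coverage are not excluded. A rate that differs between regions was not tested. DNA from somatic cells cannot be told apart, since genes that somatic cells methylate gave only 2 regions, with a median gain of 6.62 points against 9.33 at other regions. Of these genes 3.85% had an age DMR, against 15.7% of all annotated protein-coding genes, but how many of them the assay covered is unknown. An error shared by many regions of a group, such as a library batch or a few animals with raised levels, may also give this pattern, and the labels name no batch and the tables no animals, while age and exposure themselves remain open and untested.

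The second pattern is the agreement between arms at regions of higher methylation. Of its 133 gains 106 began at 30% or more in PND65 controls, where the age differences of both arms correlated with a Spearman rho of 0.392 over 528 regions, against -0.161 to 0.153 in 10000 shuffles of the BDE-47 difference among regions of like level and CpG number, which argues against chance pairing within the list. For the other 27 gains chance cannot be told apart, since they are few among 4752 regions, where rho was -0.0497 (-0.0619 to 0.0420 in shuffles). At the losses, 21 of 36 regions that lost at least 5 points in controls also fell by as much in BDE-47 animals, against 0 to 8 (mean 1.81) in shuffles among regions of like level, which argues against chance pairing within the list there too. All 5327 listed regions differed with age by at least 5 points in controls or in BDE-47 animals, and in 11 only the BDE-47 animals did. The list thus looks drawn on the differences of both arms. A list drawn on both arms can favour like signs, and the shuffles do not allow for that. The arms share no animals, and an age effect common to both arms stays open beside a batch that followed age in both arms, neither of them tested.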
